A study of Mus musculus with 12 samples.

How the data were processed

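RNA was measured in 2 populations of blood progenitors sorted from mouse bone marrow. LSK cells (Lin- Sca1+ c-Kit+) hold the stem cells and multipotent progenitors. GMP cells (Lin- Sca1- c-Kit+ CD34+ FcγR+) are the granulocyte and macrophage progenitors. The donors were 3 C57BL/6J mice with floxed Lamtor2 alleles and the Mx-Cre transgene (KO) and 3 Mx-Cre C57BL/6J mice with wild-type Lamtor2 (WT). All were injected with pIpC, which switches on Mx-Cre, and cells were sorted at day 14. RNA was extracted with the Qiagen RNeasy Micro Kit, amplified with the NuGEN WT-Ovation Pico system, labelled with biotin through the Ambion WT Expression Kit and hybridised to Affymetrix arrays, 12 in all, with 3 arrays in each of 4 groups (LSK KO, LSK WT, GMP KO and GMP WT). Which LSK and GMP samples came from the same mouse is not stated.

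Per the labels, the authors processed the arrays with RMA, which corrects background, normalises quantiles between arrays and summarises the probes of a set. Its software and version are not given in the sources used here. The deposited values were read as log2 intensities, since every array had a median between 5.96 and 6.18 and a maximum between 14.01 and 14.20. No step of normalisation was added for the main results. The table held 34760 probe sets. Of these, 22961 were listed in the probe set annotation used here and 11799 were not. A single gene symbol was found for 21640 probe sets, of which 21553 were named through their gene identifier in a table of mouse genes of assembly GRCm38.p6 and 87 kept the symbol of the annotation, and 1321 had several symbols. The files name no genome build, so no positions are given. Probe sets with a single symbol were reduced to 19937 genes. For the 954 genes with several probe sets, the set with the highest mean over the 12 arrays was used. For arrays the number of arrays limits the precision, and no count or depth lies behind a value.

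Genes were tested with limma 3.58.1 in R 4.3.3, as a single fit of the 4 groups over 12 arrays (lmFit and eBayes, neither trend nor robust option, 8 residual and 5.16 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over the 19937 genes and a threshold of 0.05. The contrasts were KO against WT in LSK, KO against WT in GMP, the difference between these effects (LSK minus GMP, the interaction), WT LSK against WT GMP, and KO LSK against KO GMP. Fold changes are on the log2 scale with the standard error (SE) of the fit, and group levels are means with the SD of 3 arrays. Each adjusted p of a gene is from limma. Lamtor2 was also tested with an exact two-sided permutation test, whose smallest p with 3 arrays against 3 is 0.1.

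Gene lists for pathways, cell types and complexes, 39 in all, were fixed in advance from general knowledge, with 1363 entries, of which 1208 were measured. The list of mitochondrially encoded transcripts had 0 measured members, so 38 lists were tested. The list test was limma's camera with a preset correlation of 0.01 and adjustment over the lists. Camera with an estimated correlation and limma's fry were run beside it. Camera asks whether the members of a list moved more than the other genes did. Fry asks whether the members moved in either sense on balance, without that comparison. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone. Where a list's call was lost with an estimated correlation, that p stands beside it.

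The genes named were chosen by a rule: Lamtor1 to Lamtor5, the 12 largest increases and 12 largest decreases past the threshold whose 3 KO arrays all lay to the same side of the 3 WT arrays, and, for each list past the threshold or with 3 or more members past it, up to 4 members with the smallest p in the direction of the list. For the interaction the 8 smallest p-values were named, and for WT LSK against WT GMP the 8 largest increases and the 8 largest decreases as well as list members. Examples from a list were taken from these. The tests, lists, naming rule and alternatives above were chosen before the data were examined.

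The KO effects in LSK and GMP were correlated across genes, with 100 relabelings of KO and WT within each cell type. Alternatives, each changing a single choice, were quantile normalisation repeated on the deposited values, arrays centred on their gene median, the dimmest 30% of genes left out, the mean of all probe sets of a gene, eBayes with trend and robust options, array weights, a fit of the 2 groups compared, a fold change of at least 1 on the log2 scale as well, replicate blocks, and each array left out in turn. Leaving out 2 arrays together, and relabelings within a replicate number, were added after the data were seen. Also added then were shufflings of the residuals of a fit with equal KO effects in LSK and GMP, and 10000 random lists per gene list, each member replaced by a gene outside the list of close rank by WT mean (the mean of both WT groups for the interaction). Members were drawn independently, so random lists lack the co-expression of real lists. Their ranges do not cover spread over arrays or mice. The gene and list steps were tested on simulated data built on the spread of these arrays. The simulated noise was independent between genes and had the same spread in every group. Its rates thus do not cover correlated genes or the wider spread of the GMP KO arrays. In the LSK simulation, over 19937 genes, 52.6% of genes shifted by 0.5 on the log2 scale were recovered, 97.2% of those shifted by 1 and 100% of those shifted by 2, with 9 false calls among 180. In the GMP simulation, over 19937 genes, these shares were 38.8%, 94.4% and 100%, with 6 false calls among 161. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and statmod 1.5.0 was used for blocks. Of the deposited probe sets, the 13120 without a single gene name were tested apart from the genes.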

Results

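Transcript levels of 19937 genes were measured in 12 arrays from bone marrow progenitors of mice in which Lamtor2 had been deleted (KO) and of WT mice, at day 14 after pIpC. Lamtor2 encodes a subunit of Ragulator, the complex on late endosomes and lysosomes that anchors the Rag GTPases and so takes part in mTORC1 signalling, and that serves as a scaffold for MEK and ERK. The 4 groups of 3 arrays were LSK KO, LSK WT, GMP KO and GMP WT. The median RMA value of an array lay between 5.96 and 6.18 on the log2 scale. No pair of arrays was identical, and the highest correlation of a pair was 0.996. GMP KO replicate 1 stood apart from its group, with a mean correlation of 0.979 with the other GMP KO arrays and an array weight of 0.19. The arrays of GMP KO deviated from their group mean by 0.215 on average (root mean square, log2), those of LSK KO by 0.138, those of LSK WT by 0.125 and those of GMP WT by 0.116.

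Lamtor2 itself had the largest decrease of all genes in both cell types. In LSK it fell by 4.97 (SE 0.17, log2), from 10.39 ± 0.09 in WT to 5.43 ± 0.33 in KO (SD, n = 3 each; limma adjusted p = 3.65e-09). The 3 LSK KO arrays read 5.11, 5.40 and 5.77, against 10.39, 10.48 and 10.31 in LSK WT. In GMP it fell by 5.54 (SE 0.17), from 10.74 ± 0.12 to 5.20 ± 0.30 (SD, n = 3 each; limma adjusted p = 8.74e-10). The 3 GMP KO arrays read 5.53, 5.12 and 4.95, against 10.80, 10.82 and 10.61 in GMP WT. The 6 KO arrays thus read 4.95 to 5.77 for a deleted gene, and throughout, a difference or fold change with 1 group mean at or below 5.77 is taken as a lower bound. The exact permutation p was 0.1 in each cell type, the smallest that 3 arrays against 3 can give. Of the other Ragulator subunits, Lamtor1 rose in GMP by 0.51 (SE 0.12, adjusted p = 0.013), and its other probe set read 0.65 higher. Without GMP WT replicate 3 the adjusted p of Lamtor1 in GMP was 0.0609, and in a fit of the 6 GMP arrays alone it was 0.0617. Lamtor3 (log2 fold change 0.35, adjusted p = 0.0643), Lamtor4 (-0.19, adjusted p = 0.453) and Lamtor5 (-0.21, adjusted p = 0.325) did not pass in GMP, and Lamtor4 read 0.0038 without GMP KO replicate 1. In LSK the fold changes of Lamtor1, Lamtor3, Lamtor4 and Lamtor5 were 0.05, 0.00, 0.03 and -0.08, none past the threshold, and the signs of Lamtor1, Lamtor3 and Lamtor4 turned in alternatives.

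**Figure D1:**
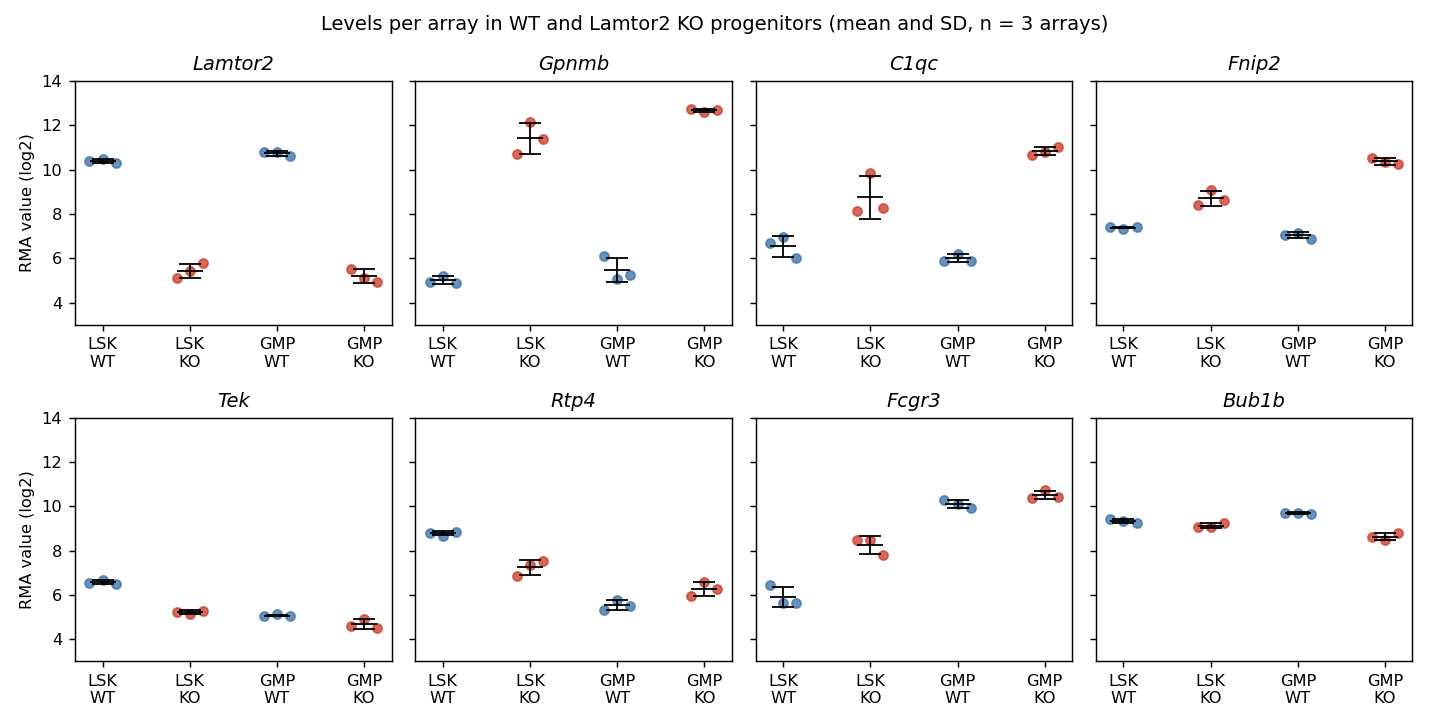
RMA values (log2, y axis) of 8 genes in each array, by cell type and genotype (x axis), with blue points for WT, red points for KO, and bars for the mean and SD of 3 arrays. Lamtor2 lies at 10.31 to 10.82 in the 6 WT arrays and at 4.95 to 5.77 in the 6 KO arrays, while Gpnmb averages 11.41 in LSK KO and 12.68 in GMP KO.

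The comparison of KO with WT in LSK asked what the loss of Lamtor2 changed in the population sorted as stem cells and multipotent progenitors. Gpnmb, a glycoprotein of late endosomes and lysosomes in macrophages, had the largest increase and rose by 6.41 (SE 0.30), to 11.41 ± 0.71 in KO (SD, n = 3; adjusted p = 1.26e-07). Ccr9, the receptor for the thymic chemokine Ccl25, rose by 3.88 (SE 0.32, adjusted p = 3.15e-05). The metallothioneins Mt1 and Mt2, which bind zinc, rose 11.8-fold and 7.97-fold, and Hpgds, which makes prostaglandin D, rose by 3.54 (SE 0.22). The WT means of Gpnmb, Ccr9 and Hpgds lay in the range of Lamtor2 in the KO arrays (4.95 to 5.77), so their increases are taken as lower bounds. The other large increases were Cd200r4 (3.48), the complement receptor C3ar1 (3.34), the aminopeptidase Anpep (3.26), the proton pump subunit Atp6v0d2 (3.08), the transglutaminase F13a1 (2.98), the granzyme Gzmb (2.89) and the chemokine Ccl3 (2.76).

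The largest decreases in KO LSK after that of Lamtor2 were those of single genes with varied functions. Mmrn1, a platelet and endothelial matrix protein, fell by 2.05 (SE 0.33), from 6.97 ± 0.97 to 4.92 ± 0.16 (SD, n = 3 each; adjusted p = 0.00303). Bgn, the proteoglycan biglycan, fell by 1.99 (SE 0.12), from 7.43 ± 0.26 to 5.44 ± 0.11 (SD, n = 3 each; adjusted p = 1.86e-06). Others were the NF-kB inhibitor Tnip3 (adjusted p = 2.69e-06), the retinaldehyde dehydrogenase Aldh1a1 (-1.94), the GTPase Gimap7 (-1.81), the cation channel Trpc6 (-1.76), endomucin (Emcn, -1.72), the tetraspanin Tspan6 (-1.71), the carbonic anhydrase Car2 (-1.62) and the interferon-inducible Ifi27l2a (-1.61). Pf4, the platelet chemokine, fell by 2.33 (SE 0.61, adjusted p = 0.0497). Leaving out any of the 6 LSK arrays ended that call, with an adjusted p of 0.0867, 0.167 and 0.118 without KO replicates 1, 2 and 3, and of 0.168, 0.182 and 0.0563 without WT replicates 1, 2 and 3.

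In all, 886 of 19937 genes passed in LSK, 496 higher and 390 lower in KO, and 182 of them changed at least 2-fold (128 higher, 54 lower). In 884 of the 886 the 3 KO arrays and the 3 WT arrays did not overlap. Over all genes 25.5% did not overlap, where chance gives 10%. The count fell by more than 1.5 times without LSK KO replicate 2 (563), LSK KO replicate 3 (455), LSK WT replicate 1 (515), LSK WT replicate 2 (468) or LSK WT replicate 3 (548). It was 643 without LSK KO replicate 1. Array weights gave 1734 genes, and a fit of the 6 LSK arrays alone gave 1390.

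Of the 38 gene lists, 18 passed in LSK with the preset correlation, 12 upward and 6 downward, and 0 with an estimated correlation. The lowest estimated-correlation value was adjusted p = 0.0523, camera with an estimated correlation gave 12 lists before adjustment, and fry gave 15. In a comparison added after the results were seen, each list's median was set against 10000 random lists matched on WT level, and 0 of the 18 lay within the central 95% of these. The lists of S phase and of lymphoid priming, not called in LSK, lay outside as well. Members of random lists were drawn independently, so these ranges do not offset the loss of the calls with an estimated correlation. Of 48 lysosomal enzymes and membrane proteins, 23 rose, 0 fell and 25 did not pass (31 rose adjusted over the list alone), with a median of 0.46 (adjusted p = 6.50e-32, or adjusted p = 0.0523 with an estimated correlation). The protease Lgmn rose by 2.65 (SE 0.24), the galactosidase Gla by 1.68 (SE 0.15) and progranulin, Grn, by 1.06 (SE 0.11). Of 17 subunits of the vacuolar ATPase, the pump that acidifies lysosomes, 8 rose and 0 fell (9 rose adjusted over the list alone), with a median of 0.34 (adjusted p = 2.85e-07, or adjusted p = 0.0866 with an estimated correlation). The subunit Atp6v0a1 rose by 0.77 (SE 0.14). In the list of cholesterol efflux and lipid storage 4 of 18 rose and 1 fell (7 and 1 adjusted over the list alone), with adjusted p = 2.15e-04 (adjusted p = 0.179 with an estimated correlation). The lipid carrier Apoe rose by 1.67 (SE 0.25).

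The list of Ragulator, Rag GTPases and mTORC1 regulators did not move as a whole in LSK (5 of 40 higher, 5 lower, the same adjusted over the list alone, adjusted p = 0.967). Its members that rose included the folliculin partners Fnip2 (1.33, SE 0.15) and Fnip1 (0.84, SE 0.10) and the Rag GTPase Rragd (1.65, SE 0.26). Fnip1 and Fnip2 act with folliculin on RagC and RagD. Of 39 genes of ribosome biogenesis and the Myc response, 7 rose and 0 fell (15 rose adjusted over the list alone), with a median of 0.24 (adjusted p = 9.41e-11, or adjusted p = 0.107 with an estimated correlation). The nucleolar Gnl3 rose by 0.56 (SE 0.09) and the transferrin receptor Tfrc by 0.65 (SE 0.11). Of 32 ERK targets and immediate early genes, 4 rose and 0 fell (5 rose adjusted over the list alone), with a median of 0.45 (adjusted p = 8.24e-07, or adjusted p = 0.147 with an estimated correlation). The ERK phosphatase Dusp4 rose by 1.27 (SE 0.14). Of 29 NF-kB targets and inflammatory cytokines, 4 rose and 0 fell (7 and 1 adjusted over the list alone), with a median of 0.22 (adjusted p = 3.70e-05, or adjusted p = 0.109 with an estimated correlation). Examples were Ccl3, Ccl2 (1.67, SE 0.23) and the NF-kB subunit Rel (0.98, SE 0.16). Of 55 genes of G2 and M phase, 1 rose and 4 fell (1 and 7 adjusted over the list alone), with a median of -0.21 (adjusted p = 7.24e-07, or adjusted p = 0.439 with an estimated correlation). Without LSK KO replicate 2 the median of G2 and M phase was -0.12, and without LSK KO replicate 3 that of ERK targets was 0.23.

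Of 38 stem cell and multipotent progenitor markers, 11 fell in KO LSK and 0 rose (19 fell and 1 rose adjusted over the list alone), with a median of -0.44 (adjusted p = 1.80e-11, or adjusted p = 0.0523 with an estimated correlation). The angiopoietin receptor Tek fell by 1.35 (SE 0.11), the imprinted gene Ndn by 1.26 (SE 0.14), the receptor Robo4 by 1.14 (SE 0.16) and Tie1 by 0.99 (SE 0.14). Of 50 type I interferon response genes, 17 fell and 0 rose (22 fell adjusted over the list alone), with a median of -0.41 (adjusted p = 1.51e-15, or adjusted p = 0.0523 with an estimated correlation). They included Ifi27l2a, Rtp4 (-1.53, SE 0.18), Ifi27 (-1.13, SE 0.11) and the GTPase Iigp1 (-1.07, SE 0.14). All mice had received pIpC, which itself induces interferon. Of 23 megakaryocyte and platelet genes, 5 fell and 1 rose (10 and 2 adjusted over the list alone), with a median of -0.27 (adjusted p = 6.24e-04, or adjusted p = 0.109 with an estimated correlation). They included Trpc6 and Mmrn1. Of 30 erythroid genes, 4 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -0.12 (adjusted p = 0.00413, or adjusted p = 0.439 with an estimated correlation). Car2 and Hemgn (-0.82, SE 0.10) were lower, and the list's adjusted p was 0.214 without LSK WT replicate 1. Of 23 B lineage genes 1 fell (5 adjusted over the list alone), with a median of -0.14 (adjusted p = 0.0186, or adjusted p = 0.439 with an estimated correlation), and its adjusted p was 0.0601 without LSK KO replicate 1, 0.0758 without LSK KO replicate 3, 0.094 without LSK WT replicate 1 and 0.113 without LSK WT replicate 2. The erythroid median was -0.20 without LSK KO replicate 1, -0.055 without LSK WT replicate 1 and -0.22 without LSK WT replicate 3, and the B lineage median was -0.057 without LSK WT replicate 1 or 2 and -0.23 without LSK WT replicate 3.

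Of 29 neutrophil primary granule and GMP markers, 10 rose in KO LSK and 0 fell (17 and 1 adjusted over the list alone), with a median of 0.39 (adjusted p = 2.12e-12, or adjusted p = 0.107 with an estimated correlation). The Fc receptor Fcgr3 rose by 2.36 (SE 0.23), the cystatin Cst7 by 1.67 (SE 0.13), Rab44 by 1.53 (SE 0.21) and Cebpa, the transcription factor needed to form GMP, by 1.23 (SE 0.15). Of 27 monocyte genes, 9 rose and 0 fell (11 and 1 adjusted over the list alone), with a median of 0.32 (adjusted p = 2.85e-07, or adjusted p = 0.147 with an estimated correlation). Among them were Mpeg1 (2.55, SE 0.27) and Ctss (1.94, SE 0.27). Of 28 macrophage genes, 9 rose and 0 fell (13 rose adjusted over the list alone), with a median of 0.67 (adjusted p = 4.34e-10, or adjusted p = 0.134 with an estimated correlation). Examples were Gpnmb, Cd68 (2.27, SE 0.21) and the transcription factor Maf (1.19, SE 0.14). The mean of the macrophage list was 7.15 in LSK KO replicate 2, 6.39 and 6.57 in LSK KO replicates 1 and 3, and 5.68 to 5.89 in LSK WT. Without LSK KO replicate 2 the macrophage median was 0.34, and without LSK KO replicate 1 or 3 the monocyte median was 0.48. Of these 28 genes, 6 are also in another list and 8 lay above the median gene in WT LSK. Macrophages inside the LSK gate cannot be told apart from a change within LSK. This also holds for the rises of lysosomal, vacuolar ATPase, lipid efflux and NF-kB genes in KO LSK. Of 21 cytokine receptors of progenitors, 6 rose and 0 fell (10 rose adjusted over the list alone), with a median of 0.29 (adjusted p = 1.20e-08, or adjusted p = 0.0523 with an estimated correlation). They included Csf2rb (1.74, SE 0.18), the signalling chain shared by the receptors for GM-CSF, IL-3 and IL-5, and Csf2rb2 (1.43, SE 0.20), a chain of the IL-3 receptor.

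Of 25 mast cell, basophil and eosinophil genes, 5 rose in KO LSK and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.23 (adjusted p = 3.63e-04, or adjusted p = 0.334 with an estimated correlation). They included the carboxypeptidase Cpa3 (2.68, SE 0.30) and the IgE receptor chain Ms4a2 (2.32, SE 0.44). Of 34 genes of neutrophil secondary granules and maturation, 5 rose and 0 fell (the same adjusted over the list alone), with a median of 0.14 (adjusted p = 0.0129, or adjusted p = 0.669 with an estimated correlation). They included the histidine decarboxylase Hdc (1.78, SE 0.32) and Trem3 (1.10, SE 0.22), and the adjusted p of that list was 0.521 without LSK KO replicate 2, 0.113 without LSK WT replicate 2 and 0.278 without LSK WT replicate 3. Its median was 0.40 without LSK KO replicate 1 or LSK WT replicate 1, -0.12 without LSK KO replicate 2, 0.075 without LSK WT replicate 2 and 0.054 without LSK WT replicate 3. The median of the mast cell, basophil and eosinophil list was 0.13 without LSK KO replicate 1 and 0.14 without LSK WT replicate 3. Lymphoid priming genes went both ways (3 of 23 higher, 4 lower, 4 and 5 adjusted over the list alone, adjusted p = 0.607), with Ccr9 higher and the receptor Notch1 (-0.94, SE 0.14) and the cytokine Ltb (-1.48, SE 0.28) lower. So did dendritic cell and MHC class II genes (3 of 25 higher, 3 lower, 4 and 7 adjusted over the list alone, adjusted p = 0.598).

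**Figure D2:**
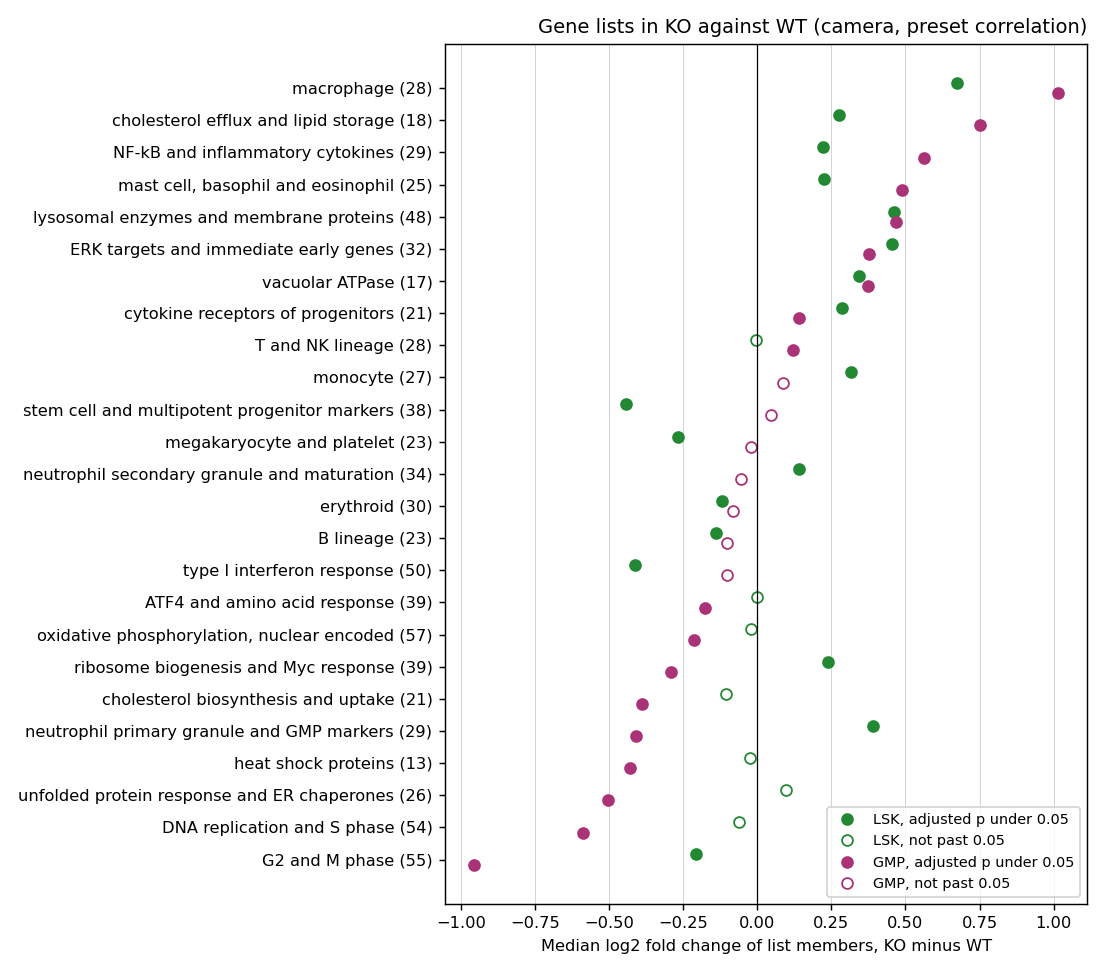
Median log2 fold change of list members, KO minus WT (x axis), for the lists past 0.05 with a preset correlation in LSK or GMP (y axis, with the number of measured members), in green for LSK and purple for GMP, with open circles for lists not past 0.05. The macrophage list has medians of 0.67 in LSK and 1.02 in GMP, and the list of G2 and M phase medians of -0.21 and -0.96.

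The same comparison in GMP asked what Lamtor2 loss changed in the population sorted as granulocyte and macrophage progenitors. Gpnmb again had the largest increase and rose by 7.20 (SE 0.30), from 5.48 ± 0.54 to 12.68 ± 0.06 (SD, n = 3 each; adjusted p = 2.01e-08). The lysosomal protease Lgmn rose by 5.04 (SE 0.24), from 5.68 ± 0.12 to 10.72 ± 0.29 (SD, n = 3 each; adjusted p = 4.54e-08). C1qc, a chain of the complement component that macrophages secrete, rose by 4.83 (SE 0.36), and Il7r, the receptor for IL-7, rose by 4.66 (SE 0.43). The WT means of Gpnmb, Lgmn and Il7r lay in or below the range of Lamtor2 in the KO arrays (4.95 to 5.77), so their increases are taken as lower bounds. The other largest increases were Anpep (5.57), Lilr4b (5.13), Ms4a7 (4.90), Ccl3 (4.88), Hpgds (4.86), C3ar1 (4.82), Atp6v0d2 (4.71) and Wfdc17 (4.68).

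The largest decrease in KO GMP after Lamtor2 was in Ifi209, an interferon-inducible gene of the HIN-200 family, which fell by 4.05 (SE 0.30), from 9.93 ± 0.09 to 5.88 ± 0.59 (SD, n = 3 each; adjusted p = 2.19e-06). The collagen-binding integrin Itga1 fell by 2.59 (SE 0.16), and Ly6a2 fell by 2.49 (SE 0.36). The others were Lrr1 (-1.93, or -1.18 without GMP KO replicate 1, adjusted p = 0.0571 in a fit of the 6 GMP arrays alone), Ms4a4c (-1.73), the glycosylation chaperone C1galt1c1 (-1.70), the Holliday junction resolvase Gen1 (-1.70), the spindle-associated Shcbp1 (-1.68), the lectin-like Klrb1f (-1.63) and the chaperone Hsph1 (-1.61). The erythroid carbonic anhydrase Car1 fell by 1.68 (SE 0.50, adjusted p = 0.036), and its adjusted p was 0.0537 without GMP KO replicate 1, 0.111 without GMP KO replicate 3, 0.132 without GMP WT replicate 1 and 0.116 without GMP WT replicate 2.

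In all, 3212 of 19937 genes passed in GMP, 1153 higher and 2059 lower, and 482 changed at least 2-fold (319 higher, 163 lower). In 3168 of the 3212 the KO and WT arrays did not overlap, and over all genes 29.6% did not overlap, where chance gives 10%. With each array centred on its gene median, 3694 genes passed, 913 higher (24.7%, against 35.9%) and 2781 lower. Without GMP WT replicate 2 the count was 1853, and a fit of the 6 GMP arrays alone gave 1778.

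Of the 38 lists, 18 passed in GMP with the preset correlation, 9 upward and 9 downward, and 0 with an estimated correlation. Camera with an estimated correlation gave 12 lists before adjustment, and fry gave 17. Of the 18 medians, 4 lay within the central 95% of random lists matched on level. They were ribosome biogenesis, oxidative phosphorylation, the ATF4 response and the T and NK lineage, so level alone could give these medians. Some lists not called in GMP lay outside as well. They were late endosome trafficking, cytosolic ribosomal proteins, type I interferon response, monocyte, erythroid and B lineage genes. Matched lists had medians of -0.22 for G2 and M phase, -0.23 for S phase, -0.22 for the unfolded protein response and -0.21 for GMP markers, so part of each fall goes with level. Of 55 genes of G2 and M phase, 54 fell and 1 did not pass (54 fell adjusted over the list alone), with a median of -0.96 (adjusted p = 1.88e-36, or adjusted p = 0.101 with an estimated correlation). The spindle checkpoint kinase Bub1b fell by 1.06 (SE 0.10), the spindle assembly factor Tpx2 by 1.19 (SE 0.13), the kinesin Cenpe by 1.22 (SE 0.13) and the topoisomerase Top2a by 1.16 (SE 0.12), whose other, dimmer probe set read 0.06. Of 54 genes of DNA replication and S phase, 42 fell and 0 rose (48 fell adjusted over the list alone), with a median of -0.59 (adjusted p = 1.29e-22, or adjusted p = 0.095 with an estimated correlation). Among them were the GINS subunits Gins3 (-1.22, SE 0.16) and Gins1 (-0.93, SE 0.12), the flap endonuclease Fen1 (-1.05, SE 0.14) and the ligase Lig1 (-0.79, SE 0.10). The cell cycle inhibitors and quiescence genes went both ways (3 of 21 higher, 3 lower, 4 and 4 adjusted over the list alone, adjusted p = 0.724), with the metabolic regulator Txnip (1.12, SE 0.12) and the antiproliferative Btg2 (1.41, SE 0.27) higher.

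Of 26 genes of the unfolded protein response and ER chaperones, 17 fell in KO GMP and 0 rose (19 fell adjusted over the list alone), with a median of -0.50 (adjusted p = 7.98e-12, or adjusted p = 0.124 with an estimated correlation). Examples were Hyou1 (-1.13, SE 0.10), Creld2 (-1.16, SE 0.12) and the disulfide isomerase Pdia6 (-0.91, SE 0.10). Of 13 heat shock proteins, 7 fell and 0 rose (7 fell adjusted over the list alone), with a median of -0.43 (adjusted p = 3.38e-05, or adjusted p = 0.261 with an estimated correlation). Of 39 genes of ribosome biogenesis and the Myc response, 17 fell and 0 rose (22 fell adjusted over the list alone), with a median of -0.29 (adjusted p = 5.98e-09, or adjusted p = 0.116 with an estimated correlation). Lists matched on level had a median of -0.24 (-0.35 to -0.13). Tfrc (-0.86, SE 0.11) and the pseudouridine synthase Dkc1 (-0.52, SE 0.10) were lower. Of 39 genes of the ATF4 and amino acid response, 16 fell and 4 rose (17 and 4 adjusted over the list alone), with a median of -0.18 (adjusted p = 0.00216, or adjusted p = 0.153 with an estimated correlation), against -0.078 (-0.20 to 0.026) in lists matched on level. The folate enzyme Mthfd2 (-1.43, SE 0.18) and the serine synthesis enzymes Phgdh (-0.83, SE 0.11) and Psat1 (-0.65, SE 0.11) were lower.

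Of 48 lysosomal enzymes and membrane proteins, 26 rose in KO GMP and 1 fell (31 and 2 adjusted over the list alone), with a median of 0.47 (adjusted p = 2.47e-18, or adjusted p = 0.095 with an estimated correlation). They included Gpnmb, Lgmn, the cholesterol transporter Npc1 (1.74, SE 0.12) and Grn (1.44, SE 0.11). Of 17 vacuolar ATPase subunits, 11 rose and 0 fell (12 rose adjusted over the list alone), with a median of 0.37 (adjusted p = 1.71e-06, or adjusted p = 0.101 with an estimated correlation). Among them were Atp6v0a1 (1.26, SE 0.14) and Tcirg1 (0.84, SE 0.14). Of 18 genes of cholesterol efflux and lipid storage, 10 rose and 1 fell (14 and 2 adjusted over the list alone), with a median of 0.75 (adjusted p = 5.38e-08, or adjusted p = 0.101 with an estimated correlation). The fatty acid carrier Fabp4 rose by 3.54 (SE 0.32) and Apoe by 3.36 (SE 0.25). Of 21 genes of cholesterol biosynthesis and uptake, 3 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -0.39 (adjusted p = 1.88e-04, or adjusted p = 0.302 with an estimated correlation). The farnesyl diphosphate synthase Fdps (-1.11, SE 0.14) and the squalene epoxidase Sqle (-0.79, SE 0.14) were lower. Of 57 nuclear-encoded genes of oxidative phosphorylation, 6 fell and 0 rose (4 fell adjusted over the list alone), with a median of -0.21 (adjusted p = 1.30e-05, or adjusted p = 0.514 with an estimated correlation), against -0.23 (-0.33 to -0.16) in lists matched on level. The complex I subunit Ndufa9 fell by 0.74 (SE 0.13). Without GMP KO replicate 1 the median of cholesterol biosynthesis was -0.17 and that of oxidative phosphorylation -0.086. In the list of Ragulator, Rag GTPases and mTORC1 regulators, 6 of 40 rose and 5 fell (8 and 9 adjusted over the list alone, adjusted p = 0.724), with Fnip2 at 3.34 (SE 0.15), Rragd at 1.89 (SE 0.26) and Rragc at 0.81 (SE 0.12).

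Of 28 macrophage genes, 16 rose in KO GMP and 0 fell (17 and 1 adjusted over the list alone), with a median of 1.02 (adjusted p = 1.16e-13, or adjusted p = 0.104 with an estimated correlation). Examples were Gpnmb, Cd68 (2.87, SE 0.21), Maf (2.05, SE 0.14), Apoe and Fabp4. The mean of this list was 7.51, 7.59 and 7.87 in the GMP KO arrays and 6.00 to 6.08 in the GMP WT arrays, and 10 of its genes lay above the median gene in WT GMP. Of 29 NF-kB targets and inflammatory cytokines, 13 rose and 0 fell (14 rose adjusted over the list alone), with a median of 0.56 (adjusted p = 5.98e-09, or adjusted p = 0.095 with an estimated correlation). They included Ccl2 (2.94, SE 0.23), the growth factor Csf1 (1.67, SE 0.19) and the NF-kB inhibitor Nfkbia (1.02, SE 0.12). Of 32 ERK targets and immediate early genes, 14 rose and 0 fell (16 and 1 adjusted over the list alone), with a median of 0.38 (adjusted p = 6.45e-09, or adjusted p = 0.116 with an estimated correlation). The transcription factor Egr1 rose by 2.73 (SE 0.39), Ier3 by 2.02 (SE 0.17) and the ERK phosphatase Dusp6 by 1.13 (SE 0.13). Of 21 cytokine receptors of progenitors, 10 rose and 1 fell (10 and 2 adjusted over the list alone), with a median of 0.14 (adjusted p = 8.37e-05, or adjusted p = 0.116 with an estimated correlation). Il7r, the progenitor receptor Flt3 (1.26, SE 0.14) and Tgfbr1 (1.15, SE 0.11) were higher, and the median of the list was 0.28 without GMP KO replicate 1 and 0.24 without GMP KO replicate 2. Of 29 neutrophil primary granule and GMP markers, 10 fell and 0 rose (11 fell adjusted over the list alone), with a median of -0.41 (adjusted p = 1.10e-04, or adjusted p = 0.340 with an estimated correlation). Among them were the serine protease Prss57 (-1.41, SE 0.15), the lectin Clec12a (-1.41, SE 0.17) and the leukotriene hydrolase Lta4h (-0.95, SE 0.11).

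Of 25 mast cell, basophil and eosinophil genes, 5 rose in KO GMP and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.49 (adjusted p = 0.00296, or adjusted p = 0.475 with an estimated correlation). Examples were the basophil proteases Prss34 (2.02, SE 0.46) and Mcpt8 (1.64, SE 0.33), and the adjusted p of the list was 0.11 without GMP KO replicate 2. Its median was 0.85 without GMP KO replicate 1, 0.18 without GMP KO replicate 2 and 0.29 without GMP WT replicate 1. Of 28 T and NK lineage genes, 3 rose and 0 fell (2 rose adjusted over the list alone), with a median of 0.12 (adjusted p = 0.00768, or adjusted p = 0.307 with an estimated correlation), against 0.063 (0.000092 to 0.13) in lists matched on level. The coreceptors Cd28 (3.20, SE 0.45) and Cd4 (2.83, SE 0.41) were higher, and the median of the list was 0.066 without GMP KO replicate 1. Monocyte genes went both ways (9 of 27 higher, 8 lower, 10 and 9 adjusted over the list alone, adjusted p = 0.604), with the lectin Lgals3 (3.60, SE 0.36) and Psap (2.16, SE 0.19) higher and Ms4a4c lower. Stem cell and multipotent progenitor markers did not pass as a list in GMP (4 of 38 higher, 2 lower, 5 and 2 adjusted over the list alone, adjusted p = 0.203), nor did type I interferon response genes (4 of 50 higher, 9 lower, the same adjusted over the list alone, adjusted p = 0.432). Only 19 of the 38 stem cell markers lay above the median gene in WT GMP, so a fall of the dimmer ones could go unseen.

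**Figure D3:**
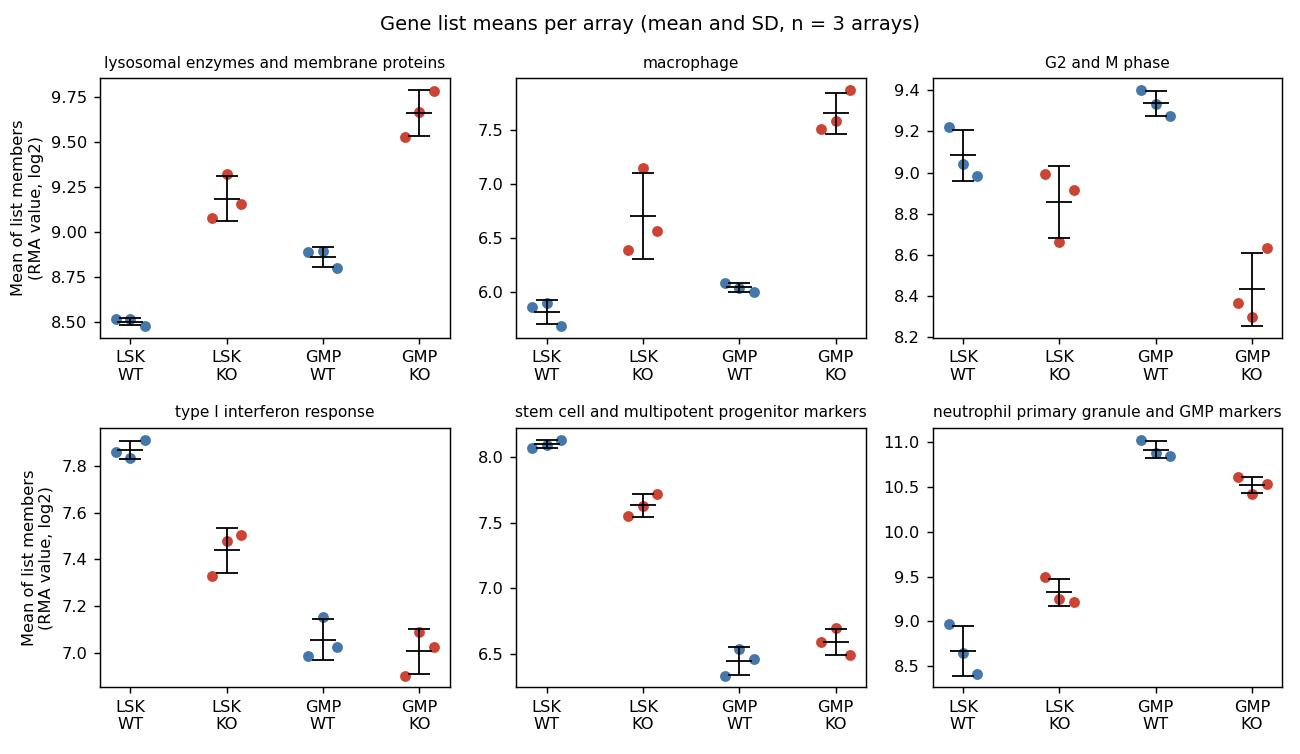
Mean RMA value of the members of 6 gene lists (log2, y axis, own scale in each panel) in each array, by cell type and genotype (x axis), with blue points for WT, red points for KO, and bars for the mean and SD of 3 arrays. The macrophage list averages 7.51 to 7.87 in the GMP KO arrays against 6.00 to 6.08 in the GMP WT arrays, and 7.15 in LSK KO replicate 2.

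Whether the KO effects of LSK and GMP differed was tested gene by gene as an interaction. Gas6, a ligand of the TAM receptors that clear dead cells, went from 5.56 ± 0.20 in GMP WT to 8.93 ± 0.36 in GMP KO, and from 6.49 ± 0.08 to 7.17 ± 0.29 in LSK (SD, n = 3 each), an LSK effect lower by at least 2.68 (SE 0.25, adjusted p = 1.82e-04). The membrane protein Emp1 (-2.79, SE 0.22) and the Ral guanine nucleotide exchange factor Rgl1 (-2.88, SE 0.26) differed in the same sense. The fatty acid enzyme Hacd4 (-2.85, SE 0.23) rose in GMP, from 5.66 ± 0.16 to 7.32 ± 0.33, and was lower in LSK KO, at 6.56 ± 0.21 against 7.75 ± 0.20 (SD, n = 3 each). The GMP WT means of Gas6 and Hacd4 lay below 5.77, so both sizes are lower bounds. The fatty acid transporter Slc27a6 (-1.97, SE 0.18) and Bgn (-1.89, SE 0.17) fell in LSK, and both GMP means of each lay below 5.77, where no change can be read, so these 2 differences may reflect background. The glutamate receptor Gria3 (1.40, SE 0.12) and the growth factor receptor Met (2.18, SE 0.20) had higher LSK than GMP effects, with Met at 8.89 ± 0.05 in GMP WT and 7.36 ± 0.22 in GMP KO (SD, n = 3 each).

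In all, 1591 genes passed the interaction, 1064 with a higher effect in LSK and 527 with a lower one. Of the 371 that differed at least 2-fold as well, 182 had a higher effect in LSK and 189 a lower one. With each array centred on its gene median 1953 passed, 1577 of them with a higher effect in LSK (80.7%, against 66.9%). The count was 800 without GMP WT replicate 2, 1012 without GMP WT replicate 3, 915 without LSK KO replicate 3, 1056 without LSK WT replicate 1 and 915 without LSK WT replicate 2. With GMP KO replicate 1 and LSK KO replicate 2 both left out, a step chosen after the data were seen, 1928 passed. Of the 485 genes called in LSK and not in GMP, 232 also passed the interaction, as did 1052 of the 2811 called in GMP and not in LSK.

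Among the lists, 18 had a different KO effect in LSK and GMP with the preset correlation, 11 higher in LSK and 7 lower, and 0 with an estimated correlation. Camera with an estimated correlation gave 6 lists before adjustment, and fry gave 12. The balance turned to 7 higher and 10 lower with quantile normalisation, 7 and 9 without GMP KO replicate 1, 10 and 11 without LSK WT replicate 3, and 7 and 8 with GMP KO replicate 1 and LSK KO replicate 2 both left out. Of the 18 medians, 6 lay within the central 95% of random lists matched on level, and some lists that were not called lay outside. Neutrophil primary granule and GMP markers moved in opposite senses in the 2 cell types, and the effect was higher in LSK for 18 of 29 and lower for 0 (22 and 0 adjusted over the list alone), with a median of 1.03 (adjusted p = 2.10e-17, or adjusted p = 0.106 with an estimated correlation). For ribosome biogenesis and the Myc response the effect was higher in LSK for 19 of 39 and lower for 0 (28 and 0 adjusted over the list alone), with a median of 0.56, against 0.25 (0.10 to 0.39) in lists matched on level (adjusted p = 7.14e-18, or adjusted p = 0.106 with an estimated correlation). G2 and M phase genes fell more in GMP, with a higher effect in LSK for 27 of 55 (40 adjusted over the list alone), with a median of 0.71 (adjusted p = 1.76e-21, or adjusted p = 0.281 with an estimated correlation). The effect was also higher in LSK for genes of S phase (17 of 54, 35 adjusted over the list alone), with adjusted p = 2.71e-16 (adjusted p = 0.144 with an estimated correlation) and for the unfolded protein response (13 of 26, 18 adjusted over the list alone), with adjusted p = 1.50e-13 (adjusted p = 0.204 with an estimated correlation). Lists matched on level had medians of 0.22 for G2 and M phase, 0.24 for S phase and 0.24 for the unfolded protein response. For GMP markers the matched median was 0.20, so part of each difference goes with level. Stem cell markers had a lower effect in LSK for 11 of 38 (13 adjusted over the list alone), with a median of -0.53 (adjusted p = 3.90e-10, or adjusted p = 0.106 with an estimated correlation). Of these markers, 33 lay above the median gene in WT LSK and 19 in WT GMP. A fall of the dimmer ones in GMP could go unseen. The random lists, matched on the mean of both WT groups, do not test this. A lower effect in LSK was also found in type I interferon genes for 14 of 50 and a higher one for 2 (18 and 3 adjusted over the list alone), with adjusted p = 2.25e-05 (adjusted p = 0.286 with an estimated correlation), and macrophage genes for 7 of 28 (9 adjusted over the list alone), with adjusted p = 4.94e-05 (adjusted p = 0.362 with an estimated correlation). The lysosomal list (3 of 48 higher, 4 lower, 5 and 6 adjusted over the list alone, adjusted p = 0.351) and the vacuolar ATPase (0 of 17 past, 2 lower adjusted over the list alone, adjusted p = 0.351) did not pass camera. Both medians still lay below those of lists matched on level. The lysosomal median was -0.048 against 0.16 (0.027 to 0.30), and that of the vacuolar ATPase -0.12 against 0.24 (0.0083 to 0.45). The random lists were drawn gene by gene and do not cover spread over arrays or mice. No difference between LSK and GMP is thus concluded for either list.

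The effects in the 2 cell types were compared across genes, which are not independent replicates. Their Pearson correlation was 0.41 and their Spearman correlation 0.10, and 1 of 100 relabelings, the real one, gave a Pearson correlation as high, the highest other being 0.31. The labels were exchanged separately in LSK and GMP. Variation shared by LSK and GMP arrays of the same mouse was thus not kept, and could itself correlate the effects. With replicate number as a fixed term in the fit, the share of relabelings as high was 0.15, which does not pass 0.05. Both cell types called 401 genes, 336 of them in the same direction. There were 228 genes higher in both, such as Gpnmb, Lgmn and Fnip2, where independent lists would share 28.7, and 108 lower in both, such as Lamtor2 and Car2, where they would share 40.3. Genes higher in LSK and lower in GMP, such as Tfrc, numbered 51 (51.2 for independent lists), and 14 were lower in LSK and higher in GMP (22.6 for independent lists).

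**Figure D4:**
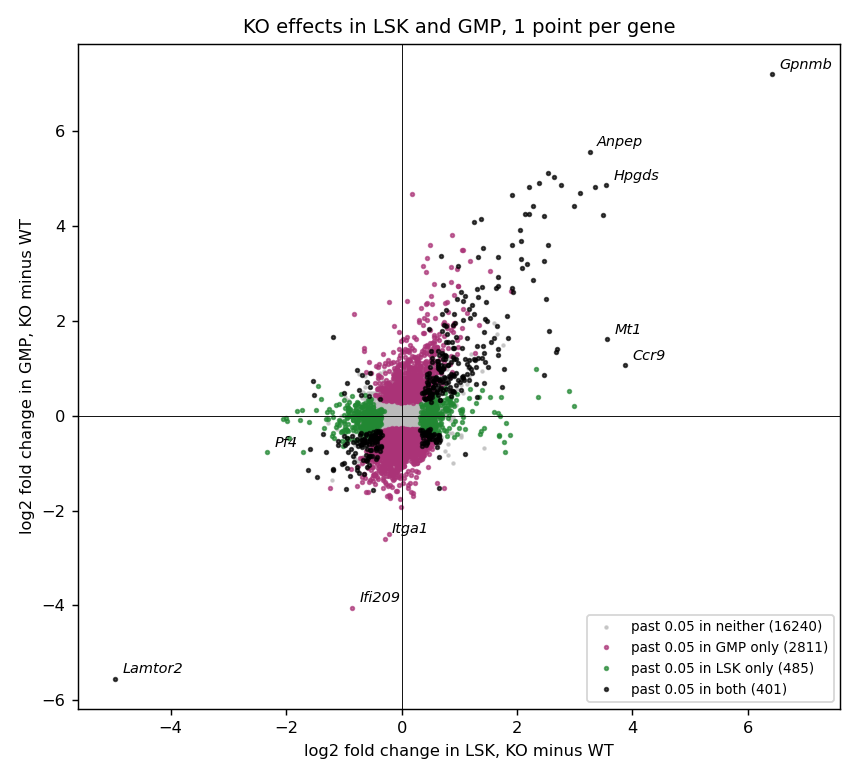
Log2 fold change in GMP (y axis) against that in LSK (x axis), KO minus WT, for 19937 genes, in black where both cell types passed 0.05 (401), green for LSK alone (485), purple for GMP alone (2811) and grey for neither. Gpnmb lies at 6.41 and 7.20, Lamtor2 at -4.97 and -5.54, and the Pearson correlation across genes is 0.41.

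WT LSK and WT GMP were compared to describe the step from multipotent to granulocyte and macrophage progenitors in control mice. Dntt, the terminal transferase of early lymphoid cells, was higher in LSK by 5.53 (SE 0.28), at 11.02 ± 0.17 against 5.50 ± 0.30 (SD, n = 3 each; adjusted p = 4.54e-08). This is taken as a lower bound, since the GMP mean lay in the range of Lamtor2 in the KO arrays (4.95 to 5.77). The stem cell transcription factors Hlf (3.43, SE 0.13) and Mecom (3.23, SE 0.22), Gimap6 (3.85), Car2 (3.63), Wfdc17 (3.52), Ctla2a (3.32) and Rtp4 (3.24) were also higher in LSK. Higher in GMP were F13a1 (-5.02, SE 0.40), the granule genes Ms4a3 (-4.88), Elane (-4.81), Prg2 (-4.38) and Hp (-4.07), Ly86 (-4.48), the Fc receptor gene of the GMP gate, Fcgr3 (-4.20, SE 0.23), and Ifi209 (-4.03). In all, 3905 genes passed, 2047 higher in LSK and 1858 higher in GMP, and 846 differed at least 2-fold. Over all genes 40.6% did not overlap, where chance gives 10%. With each array centred on its gene median, 4552 passed, 1563 higher in LSK (34.3%, against 52.4%).

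Of the 38 lists, 25 passed between WT LSK and WT GMP with the preset correlation, and 4 with an estimated correlation. They were stem cell and multipotent progenitor markers (35 of 38 higher in LSK, 0 lower, the same adjusted over the list alone), with a median of 1.66 (adjusted p = 0.0065 with an estimated correlation), and neutrophil primary granule and GMP markers (27 of 29 lower, 0 higher, the same adjusted over the list alone), with a median of -2.21 (adjusted p = 0.0185 with an estimated correlation). The others were megakaryocyte and platelet genes (14 of 23 higher, 0 lower, 16 and 0 adjusted over the list alone), with a median of 0.96 (adjusted p = 0.0185 with an estimated correlation) and type I interferon response genes (34 of 50 higher, 3 lower, 37 and 4 adjusted over the list alone), with a median of 0.75 (adjusted p = 0.0292 with an estimated correlation). Esam (2.45, SE 0.14), Gcnt2 (2.88, SE 0.16), Zfpm1 (1.60, SE 0.14) and Iigp1 (2.88, SE 0.14) were higher in LSK, and Alas1 (-3.07, SE 0.15) and Anxa3 (-3.55, SE 0.18) higher in GMP. Monocyte genes were lower in LSK for 16 of 27 and higher for 2 (17 and 2 adjusted over the list alone), with a median of -0.92 (adjusted p = 1.09e-10, or adjusted p = 0.101 with an estimated correlation). The transcription factor Irf8 was higher in GMP (-2.31, SE 0.13). Lymphoid priming genes were higher in LSK for 13 of 23 and lower for 1 (15 and 1 adjusted over the list alone), with a median of 0.82 (adjusted p = 5.79e-10, or adjusted p = 0.0785 with an estimated correlation). Flt3 was higher in LSK (2.89, SE 0.14).

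The same populations were compared in KO mice. Stem cell and multipotent progenitor markers were higher in KO LSK than in KO GMP for 27 of 38 and lower for 0 (31 and 0 adjusted over the list alone), with a median of 0.85 (adjusted p = 0.0331 with an estimated correlation), and neutrophil primary granule and GMP markers were lower for 23 of 29 and higher for 0 (24 lower adjusted over the list alone), with a median of -1.07 (adjusted p = 4.49e-18, or adjusted p = 0.121 with an estimated correlation). Dntt read 10.53 ± 0.73 in KO LSK and 4.77 ± 0.24 in KO GMP, and Elane 9.19 ± 1.03 and 12.52 ± 0.25 (SD, n = 3 each). Macrophage genes were lower in KO LSK for 16 of 28 and higher for 1 (18 and 1 adjusted over the list alone), with a median of -0.96 (adjusted p = 2.36e-09, or adjusted p = 0.171 with an estimated correlation), and G2 and M phase genes were higher for 25 of 55 and lower for 0 (39 and 0 adjusted over the list alone), with a median of 0.44 (adjusted p = 1.33e-13, or adjusted p = 0.327 with an estimated correlation). In all, 3160 genes passed, 2006 higher in KO LSK and 1154 higher in KO GMP, and 497 differed at least 2-fold. Over all genes 31.5% did not overlap, where chance gives 10%. The count was 1667 without LSK KO replicate 3, 1327 in a fit of the 6 KO arrays alone, and 2702 with GMP KO replicate 1 and LSK KO replicate 2 both left out.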

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

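The tests of equal KO effects, lists matched on level, single arrays, cell mixtures, dilution and compression were chosen after the results were seen.

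The KO effects of LSK and GMP differed for 1591 genes by the interaction test. In relabelings of KO and WT within each cell type, 2 of 100 gave as many, the real one and the one that exchanged KO and WT in all GMP arrays (2430). The highest of the other 98 gave 914, and these relabelings test for no KO effect in either cell type, not for equal effects. Equal effects were tested by 100 shufflings of the residuals of a fit with the same KO effect in both. Of these only the real one, 1 of 100, gave as many (highest other 1). The shufflings treat arrays as independent and of equal spread. LSK and GMP arrays may share a mouse, and the mean deviation was 0.215 in GMP KO against 0.116 in GMP WT. Chance is thus argued against only under those assumptions, and cannot be excluded for arrays that share a mouse. For the remaining comparisons the 6 arrays have 10 splits, of which only the real one, 1 of 10, gave as many genes, and a share under 0.05 cannot be reached. The real split gave 886 in LSK (highest other 1), 3212 in GMP (0), 3905 between WT LSK and WT GMP (0) and 3160 between KO LSK and KO GMP (1).

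By the same test the 8 genes with the smallest p differed by -2.79 in Emp1, -2.85 in Hacd4, 1.40 in Gria3, -2.88 in Rgl1, 2.18 in Met, -1.89 in Bgn, -1.97 in Slc27a6 and -2.68 in Gas6 (LSK minus GMP effect, log2). The median difference of a list was 0.71 for G2 and M phase, 0.56 for ribosome biogenesis and Myc response, 1.03 for neutrophil primary granule and GMP markers, 0.51 for DNA replication and S phase and 0.64 for the unfolded protein response. In the same order these had adjusted p = 0.281, 0.106, 0.106, 0.144 and 0.204 with an estimated correlation. Random lists matched on level had medians of 0.22, 0.25, 0.20, 0.24 and 0.24 in that order, so part of each difference goes with level. The median difference was -0.53 for stem cell and multipotent progenitor markers, -0.34 for type I interferon response, -0.59 for macrophage genes, 0.37 for heat shock proteins, -0.48 for cholesterol efflux, 0.19 for the ATF4 response and -0.20 for NF-kB. In that order these had adjusted p = 0.106, 0.286, 0.362, 0.362, 0.316, 0.281 and 0.316 with an estimated correlation. The difference of the stem cell markers may in part reflect dim genes, since 19 of 38 lay above the median gene in WT GMP. Without single arrays the macrophage median was -0.36 (LSK KO replicate 1), and that of NF-kB was -0.13 (GMP KO replicate 3) and -0.31 (LSK KO replicate 3). The GMP WT means of Gas6 and Hacd4, and both GMP means of Bgn and Slc27a6, lay below 5.77, the highest value of Lamtor2 in a KO array. Random lists matched on level had medians of 0.14 (-0.059 to 0.38) for heat shock proteins and 0.075 (-0.049 to 0.23) for the ATF4 response, so level alone could give these differences.

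The 6 other lists that differed lost that call without single arrays. They were oxidative phosphorylation (0.15, preset adjusted p = 0.163 without GMP KO replicate 1), megakaryocyte and platelet genes (-0.28, 0.0859 without LSK KO replicate 2), ERK targets (-0.12), monocyte genes (0.46), cholesterol biosynthesis (0.25) and glycolysis (0.16). In that order these had adjusted p = 0.585, 0.316, 0.548, 0.556, 0.548 and 0.362 with an estimated correlation. The median of oxidative phosphorylation was 0.050 without GMP KO replicate 1, 0.24 without GMP KO replicate 3 and 0.096 without LSK KO replicate 1. That of megakaryocyte and platelet genes was -0.085, -0.15 and -0.17 without GMP KO replicate 2, GMP WT replicate 2 and LSK KO replicate 2, and that of ERK targets was -0.057 and -0.22 without LSK KO replicates 1 and 3. That of monocyte genes was 0.13 without GMP KO replicate 1 and 0.27 without LSK KO replicate 2, and that of cholesterol biosynthesis was 0.14 and 0.42 without GMP KO replicates 1 and 3. Random lists matched on level had medians of 0.26 (0.15 to 0.36) for oxidative phosphorylation, -0.00025 (-0.13 to 0.14) for ERK targets, 0.075 (-0.11 to 0.29) for cholesterol biosynthesis and 0.15 (-0.044 to 0.36) for glycolysis, so level alone could give these differences. The adjusted p of ERK targets with the preset correlation was 0.125 without GMP KO replicate 3, 0.138 and 0.132 without LSK KO replicates 1 and 2, and 0.0508 without LSK WT replicate 1. For monocyte genes it was 0.177 without GMP KO replicate 1, 0.101 without GMP WT replicate 1 and 0.328 without LSK KO replicate 2. For cholesterol biosynthesis it was 0.475 without GMP KO replicate 1, 0.0647 and 0.0505 without GMP WT replicates 2 and 3, 0.124 without LSK KO replicate 3, and 0.0853 and 0.074 without LSK WT replicates 1 and 2. For glycolysis it was 0.0842 and 0.0518 without GMP KO replicates 1 and 2, 0.0897 without GMP WT replicate 2, 0.0509 and 0.0574 without LSK KO replicates 2 and 3, and 0.0564 and 0.0598 without LSK WT replicates 1 and 3.

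Among 13120 probe sets with no single gene name, tested apart with limma, 22 changed in LSK (12 higher, 10 lower) and 456 in GMP (329 higher, 127 lower).

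Macrophage genes were higher in KO GMP, with 16 of 28 past the threshold (adjusted p = 0.104 with an estimated correlation). Macrophages inside the GMP gate cannot be told apart from a change within GMP, since the profile of KO macrophages was not measured. A Lin- c-Kit+ gate is meant to exclude macrophages, but the purity of the sort was not tested here. The same holds for macrophages inside the LSK gate. Of the 28 genes, 10 lay above the median gene in WT GMP and 6 are in another list, and of genes picked after their values were seen, Apoe (12.47 in GMP KO), Cd68 (11.98) and C1qb (10.02) rose while Csf1r (-0.09, adjusted p = 0.888) and Vcam1 (-0.09, adjusted p = 0.860) did not pass. A single unusual array is argued against, since the lowest KO array lay 1.43 above the highest WT array in the list mean. A macrophage-like programme in GMP without Lamtor2 may be present as well, and was not tested.

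G2 and M phase genes were lower in KO GMP, with a median of -0.96 (adjusted p = 0.101 with an estimated correlation). Dilution by non-dividing cells was weighed with genes whose WT GMP means lay between 8 and 12. There 20 GMP markers fell less than 48 G2 and M phase genes, by a difference of 0.55 (0.26 to 0.87). That interval is a bootstrap over genes, not over arrays or mice. It argues only against dilution by cells without GMP markers as the whole cause, since cells that carry these markers would also make them fall less. Compression of the KO GMP arrays is argued against as the whole cause only, since 10000 random lists matched on level also fell, with a median of -0.22 (-0.32 to -0.13) and a lowest of -0.40. A single array is argued against by a gap of -0.64 between the highest KO and the lowest WT array. Slower division of GMP without Lamtor2 may underlie the pattern, but it was not tested.

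Stem cell and multipotent progenitor markers were lower in KO LSK for 11 of 38 (adjusted p = 0.0523 with an estimated correlation). GMP cells inside the LSK gate, which the Sca1 gate is meant to exclude, are argued against as the whole cause by a median over genes only. The 26 genes used, at least 8 times higher in WT GMP, implied a median share of KO GMP RNA of 15.6% (7.98 to 18.1, bootstrap over genes). This lies below the 26.4% that the median fall of the stem cell markers would need if GMP RNA held none of these transcripts. No interval was computed for that share. Any of these transcripts in GMP RNA would raise the share needed. Single genes ran from -12.6% (Clec12a) to 40.1% (Ccr2), and the median was 8.68% with WT GMP as the source. Of the 29 GMP markers, 27 lay above the median gene in WT LSK and 4 are in another list, and Elane read 9.19 in LSK KO against 12.52 in GMP KO. A single array is argued against by a gap of -0.35 between the highest KO and the lowest WT array, and a smaller GMP share together with a change within LSK may both contribute, which was not tested.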

How the results depend on the processing

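The settings that left out GMP KO replicate 1 and LSK KO replicate 2 together, and the relabelings within a replicate number, were chosen after the data were seen. Among values that answer a comparison, 104 kept their direction and side of the threshold, or a count within 1.5 times, under alternatives other than leaving out an array, 13 moved and 1 was lost. Array weights gave 1734 genes in LSK, and the arrays of the 2 groups compared gave 1390 in LSK, 1778 in GMP and 1327 between KO LSK and KO GMP. A fit of 2 groups has the same fold changes by construction and differs only in its estimate of spread and degrees of freedom. The main fit shares that estimate over arrays that deviated by 0.215 in GMP KO, 0.138 in LSK KO, 0.125 in LSK WT and 0.116 in GMP WT. The main counts of LSK and GMP are thus not a like measure of the extent of change. Why array weights raised the LSK count was not tested. A fold change of at least 1 on the log2 scale as well, a stricter criterion by construction, left 182 genes in LSK, 482 in GMP, 371 in the interaction, 846 between WT LSK and WT GMP and 497 between KO LSK and KO GMP. With an estimated correlation 0 lists passed camera in LSK, 0 in GMP, 0 in the interaction and 4 between WT LSK and WT GMP. Without single arrays, the counts ran from 455 to 643 in LSK, from 1853 to 3628 in GMP, from 800 to 2006 for the interaction, from 2980 to 3206 between WT LSK and WT GMP and from 1667 to 4044 between KO LSK and KO GMP, and fewer arrays were fitted in each.

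The replicate numbers do not show which samples share a mouse. Of 12 pairs with the same number, 4 deviated together with a correlation over 0.1 (range -0.18 to 0.28), and in 6 of the 12 pairs a sample correlated best with the sample of its own number in the other group. These pairs include KO with WT of the same cell type, which cannot share a mouse. For replicates 1, 2 and 3, LSK with GMP read 7.22e-04, -0.18 and 0.15 in KO and 0.18, -0.027 and 0.080 in WT. Of these, only LSK WT replicates 1 and 3 correlated best with their own number. With replicate number as a fixed block the counts were 852 in LSK, 3073 in GMP, 1511 for the interaction, 3837 between WT LSK and WT GMP and 3027 between KO LSK and KO GMP. In that planned block fit the correlation of KO effects was 0.41 and 0.15 of the 100 relabelings were as high, so its call was lost. After that result was seen, KO and WT were exchanged within a replicate number only, and 1 of 32 relabelings, the real one, was as high (share 0.0312, highest other 0.33). These exchanges were also made separately in LSK and GMP, so they do not keep variation shared by arrays of the same mouse. With array weights the correlation was 0.43 (share 0.04), and in 30 of those 100 relabelings, the real one not among them, the weights stopped before convergence. Without single arrays it ran from 0.34 to 0.44.

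The sign of Lamtor3 in LSK turned with quantile normalisation (-0.072), and so did that of Lamtor4 in LSK (-0.044), neither past the threshold. Without single arrays, Lamtor1 in LSK ran from -0.027 to 0.094, Lamtor3 in LSK from -0.039 to 0.077, Lamtor4 in LSK from -0.053 to 0.088 and Lamtor4 in GMP from -0.32 to 0.0038. Lamtor2 ran from -5.14 to -4.81 in LSK and from -5.71 to -5.42 in GMP. Of list results, 641 kept their call under other alternatives and 113 lost it, and 540 kept it and 42 lost it without single arrays. Of results for named genes, 3817 kept their call under other alternatives, 64 lost it and 41 gained it, and without single arrays 2329 kept it, 220 lost it and 10 gained it. Among called genes with several probe sets, the sets had fold changes of opposite sign for 9 of 57 in LSK and 32 of 201 in GMP. Signal over background limits what dim genes can show.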

Other observations

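The tests reported in this part were all planned. Genes that carry lysosomes along microtubules and fuse them moved both ways in KO GMP. In the list of BORC, HOPS, CORVET and late endosome trafficking, 4 of 37 rose and 3 fell (6 and 7 adjusted over the list alone, adjusted p = 0.966), among them the lysosome adaptors Plekhm2 (1.07, SE 0.12) and Plekhm1 (0.74, SE 0.10). In LSK 2 rose and 0 fell (the same adjusted over the list alone, adjusted p = 0.0587). Of 45 autophagy genes 5 rose and 5 fell in GMP (the same adjusted over the list alone, adjusted p = 0.994), with the autophagosome factor Tecpr1 (1.82, SE 0.13) and the cargo receptor Sqstm1 (0.97, SE 0.09) higher, and 2 rose in LSK (2 adjusted over the list alone, adjusted p = 0.407).

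The lists of p53 targets, apoptosis regulators and NRF2 targets did not pass camera in either cell type. Of 36 p53 targets, 7 rose and 8 fell in GMP (8 and 8 adjusted over the list alone, adjusted p = 0.891), and 2 rose and 4 fell in LSK (3 and 6 adjusted over the list alone, adjusted p = 0.144). Of 32 apoptosis regulators, 4 rose and 6 fell in GMP (the same adjusted over the list alone, adjusted p = 0.955), among them the survival factor Bcl2 (-0.49, SE 0.10) and Bid (-0.72, SE 0.12), and 1 fell in LSK (1 adjusted over the list alone, adjusted p = 0.0587). Of 29 NRF2 and oxidative stress genes, 4 rose and 6 fell in GMP (5 and 8 adjusted over the list alone, adjusted p = 0.724), with the pentose phosphate enzymes Pgd (-0.81, SE 0.11) and Taldo1 (-0.74, SE 0.11) lower, and 2 rose in LSK (4 and 2 adjusted over the list alone, adjusted p = 0.143). Of 19 glycolysis genes, 1 rose and 3 fell in GMP (1 and 5 adjusted over the list alone, adjusted p = 0.109). Of 16 genes of fatty acid synthesis 1 rose and 1 fell in GMP (the same adjusted over the list alone, adjusted p = 0.697). Of 27 genes of marrow stroma and endothelium 1 fell in GMP (1 adjusted over the list alone, adjusted p = 0.405), and 1 rose and 3 fell in LSK (2 and 3 adjusted over the list alone, adjusted p = 0.598). Of 54 cytosolic ribosomal proteins 0 passed in limma in GMP (0 adjusted over the list alone, camera adjusted p = 0.724).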
